A study of Mus musculus with 4 samples.

How the data were processed

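Ribosome-protected RNA fragments were measured in whole brains of C57BL/6J mice at postnatal day 21. In the Snap25 line a GFP-tagged ribosomal protein, Rpl10a, is made in neurons, and in the Aldh1l1 line it is made in astrocytes. Tagged ribosomes were captured with antibodies to GFP and digested with RNase I on the beads, so that the sequenced fragments are footprints of ribosomes from the tagged cell type, per the labels' protocols. Each of the 4 libraries, 2 per cell type, came from 2 pooled brains and was made in a separate experiment of its group, per the labels. The p-values below therefore measure the spread between pools, with 2 pools per cell type.

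The deposited values are whole-number counts of fragments, 1 count per transcript region, with no normalization visible in the values. Each region is named by an Ensembl mouse transcript ID followed by a letter, a, b, c or d, and a region without a count has no line, so that absent regions were read as 0. The meaning of the letters, the genome build, the annotation, the use of strand and the treatment of fragments that fit several transcripts are not given in the sources used here. The tools named are FastQC 0.11.2, Trimmomatic 0.32, STAR 2.3.1z8, Bowtie2 2.2.2, bedtools and edgeR, per the submitters' processing notes, which give no role or order for them. Sequencing covered several lanes and the reads of a sample were joined across lanes, per the labels.

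The files do not pair transcripts with genes, and the tables of gene names at hand hold no transcript IDs, so 0 of the 23175 transcripts could be given a gene name. The design fixed before the data were examined called for counts per gene. In its place the counts of a transcript were summed over its 4 regions and tested per transcript. The tests of cell type marker and pathway lists, the shares of counts on marker lists, the values of Snap25, Aldh1l1 and Rpl10a and the removal of mitochondrially encoded genes need gene names and were not run. Without Snap25 and Aldh1l1 the labels of the libraries could not be checked against marker genes.

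Many transcripts carry the same counts. Of the 17836 transcripts with at least 50 region b counts over all libraries, 4634 shared all 4 library counts of region b with another transcript, in 1983 sets of up to 9 members. Repeats of a set already counted held 12.25% to 12.6% of the region b counts of a library, so the same fragments may enter the totals more than once, and numbers of transcripts are not numbers of genes. Beside the main counts, numbers of distinct profiles of region b counts are given. Only identical region b counts were merged, so transcripts with nearly the same counts still count as separate profiles.

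Transcripts that passed the edgeR filterByExpr rule, with a minimum count of 10, were compared between neuron and astrocyte samples with the edgeR 4.0.16 quasi-likelihood F test in R 4.3.3. TMM factors scaled the libraries, cell type was the only term, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Standard errors are the size of the fitted log2 fold change divided by the square root of F. Levels per library are given as CPM, the count scaled to a common library total. Correlations between libraries used log2 CPM with a prior count of 2. The share of counts in each region was compared with a two-sided exact permutation test, which cannot go below p = 0.333 with 2 against 2 libraries.

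The ratio of region a, c or d to region b was tested per transcript in a quasi-likelihood model over the counts of both regions, with a term for each library, a term for the region and the interaction of region and cell type. Both regions of a library carried the same library total as offset, so a shift of a region over all transcripts stays in the ratios. Shares at equal transcript weights were computed over the 13108 transcripts with at least 50 region b counts in every library, each weighted by its counts summed over the 4 libraries. They are shares of the counts of that region and region b together. Region levels as a percentage of region b were taken over the 7382 transcripts with at least 1000 region b counts.

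The rule for named items was fixed before the data were examined: the 12 highest and the 12 lowest log2 fold changes among called transcripts with a mean of at least 10 CPM and no overlap between the groups, and the 5 most abundant. As the IDs carry no gene names, 2 IDs per direction are printed, ranks 1 and 4, since the ranks between them in each direction have nearly the counts of rank 1. Any other ID was chosen after its values were seen.

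The library totals of 7210269 to 12833187 counts gave narrow 95% Wilson intervals on region shares. These intervals, and the limit of 3 counts that a count of 0 allows, cover counting error only. Both tests were tested on simulated counts with 200 transcripts changed by known folds. For transcript totals these were drawn from the real means and library totals, and for the ratio from the observed region b counts of each library. Both cell types were given the same spread, although the real neuron libraries differed more from each other than the astrocyte libraries did. The rates below hold for equal spread only. For the neuron and astrocyte comparison of transcript totals, 97.0% of simulated 4-fold changes, 66.7% of 2-fold and 11.9% of 1.5-fold changes were called in the right direction, among 18607 transcripts. For the region a to region b ratio, 86.0% of 4-fold changes, 19.7% of 2-fold and 0 of 59 1.5-fold changes were called, among 8722 transcripts.

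The alternatives were other scaling factors (RLE, upper quartile, library totals alone), no filter or a mean of at least 10 CPM, DESeq2 1.42.0, limma-voom (limma 3.58.1), a replicate block, thinning to the smallest library, removal of the 20 most abundant transcripts, a minimum fold of 1.5, and each library left out in turn. Region b counts alone, 1 transcript per set of identical counts, a crossed replicate pairing and most alternatives of the ratio tests were chosen after seeing the data. The fixed design held a region ratio test only for files that count untranslated regions and coding sequence separately. As the regions here are not named, the ratio tests of regions a, c and d to region b lay outside that design.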

Results

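Ribosome footprints were collected from neurons and astrocytes of the postnatal day 21 mouse brain to compare what the cell types translate and where on each transcript ribosomes lie. The astrocyte libraries 1 and 2 held 7292950 and 7968406 counts, and the neuron libraries 1 and 2 held 7210269 and 12833187. Of 23175 transcripts with a count in any library, 21785 to 22150 had a count in a given library. The astrocyte libraries drew more of their counts from few transcripts. The 100 most abundant transcripts took 17.73% and 18.47% of the astrocyte counts, against 13.82% and 12.14% of the neuron counts. The most abundant transcript of a library took 1.037% and 1.13% in the astrocyte libraries and 0.3242% and 0.4103% in the neuron libraries.

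Across 18819 transcripts, which are not independent replicates, log2 CPM correlated with Pearson r = 0.987 between the astrocyte libraries and r = 0.971 between the neuron libraries. Between cell types r lay between 0.91 and 0.945. The SD of the log2 differences was 0.31 between the astrocyte libraries and 0.493 between the neuron libraries. Neuron 1 lay nearer to the astrocyte libraries (SD 0.656 and 0.686) than neuron 2 did (SD 0.815 and 0.854). In a check for libraries deposited more than once, the chi-square of the counts per degree of freedom was 2.1 for the astrocyte pair and 22.1 for the neuron pair, so the counts of neither pair agreed within sampling noise.

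The first comparison asked which transcripts carried more footprints in which cell type. Of the 18819 transcripts tested, 797 were higher in neuron and 2422 were higher in astrocyte samples. The changes toward astrocytes were also larger. At least 2-fold changes numbered 234 higher in neuron and 1761 higher in astrocyte samples, and at least 4-fold changes numbered 39 and 551. The transcripts called higher in astrocyte samples took 24.45% and 25.4% of the counts of the astrocyte libraries and 9.508% and 7.541% of those of neuron 1 and neuron 2. Those called higher in neuron samples took 9.404% and 12.09% of the counts of neuron 1 and neuron 2 and 5.613% and 5.501% of those of the astrocyte libraries.

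**Figure D1:**
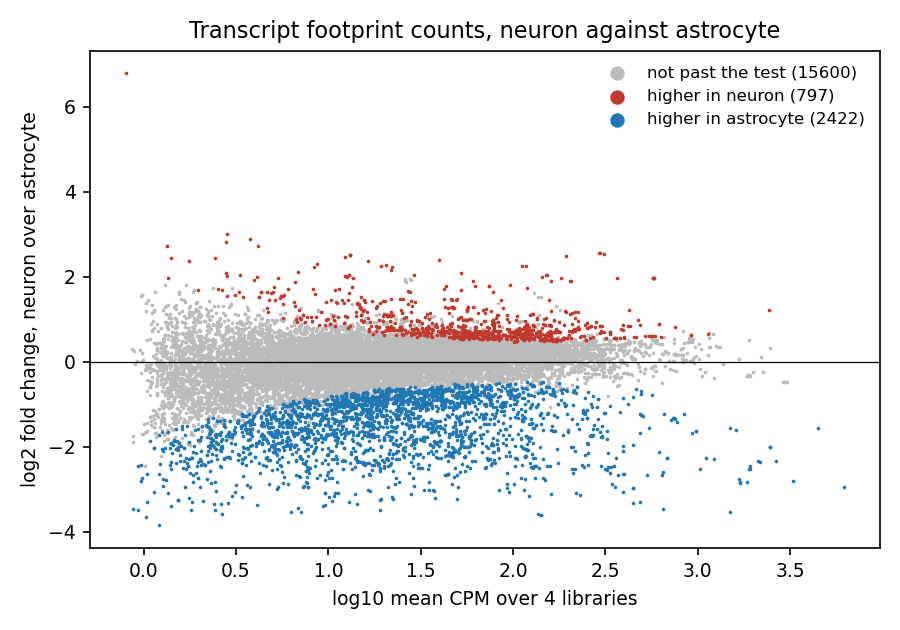
Each point is a tested transcript, with the log10 of its mean CPM over the 4 libraries on the horizontal axis and the log2 fold change of neuron over astrocyte on the vertical axis. Red points are the 797 transcripts called higher in neuron samples and blue points the 2422 called higher in astrocyte samples by the edgeR quasi-likelihood test.

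The 12 called transcripts with the highest fold changes at a mean of at least 10 CPM were 4.79-fold to 5.902-fold higher in neuron samples. They had 10 distinct profiles of region b counts. The 12 at the other end were 9.51-fold to 12.2-fold higher in astrocyte samples, also with 10 distinct profiles. In both directions some of these profiles were nearly alike, so they are not all separate findings. ENSMUST00000171533 measured 510.9 ± 321.9 CPM in neuron and 79.43 ± 2.47 CPM in astrocyte samples (SD, n = 2 each), a log2 fold change of 2.56 (SE 0.384, edgeR adjusted p = 0.00348). ENSMUST00000169776, whose counts all lay in region b, measured 22.51 ± 16.54 CPM in neuron and 3.69 ± 0.60 CPM in astrocyte samples (SD, n = 2 each), a log2 fold change of 2.52 (SE 0.52, edgeR adjusted p = 0.0139). ENSMUST00000108110 measured 23.41 ± 12.39 CPM in neuron and 258.6 ± 12.63 CPM in astrocyte samples (SD, n = 2 each), a log2 fold change of -3.61 (SE 0.338, edgeR adjusted p = 0.000461). ENSMUST00000034215 measured 256.5 ± 129.2 CPM in neuron and 2735 ± 180.7 CPM in astrocyte samples (SD, n = 2 each), a log2 fold change of -3.53 (SE 0.356, edgeR adjusted p = 0.000598). Region a held 34.51% of the counts of this last transcript. For all 4 the neuron libraries themselves lay over 2-fold apart. In neuron 1 and neuron 2 they measured 283.3 and 738.6 CPM for ENSMUST00000171533, 10.82 and 34.21 CPM for ENSMUST00000169776, 32.18 and 14.65 CPM for ENSMUST00000108110 and 347.8 and 165.1 CPM for ENSMUST00000034215. In the same order, the log2 fold changes were 3.08, 3.08, -4.28 and -4.19 without neuron 1 and 1.74, 1.46, -3.10 and -3.07 without neuron 2.

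Of the 5 most abundant transcripts, 3 were higher in astrocyte samples, with log2 fold changes of -2.95, -1.57 and -2.82. The most abundant of all measured 10370 and 11300 CPM in the astrocyte libraries and 1925 and 1119 CPM in neuron 1 and neuron 2 (edgeR adjusted p = 0.00075). The other two had log2 fold changes of -0.47 and adjusted p = 0.231 and 0.223, and did not pass the test. In CPM without TMM factors, the groups did not overlap in 65.8% of the tested transcripts, where chance gives 33.3% on average. All transcripts come from the same 4 libraries and are not independent, so this share was not tested against chance. At an unadjusted p under 0.05 there were 6062 transcripts. The calls held 676 distinct profiles of region b counts higher in neuron and 2049 higher in astrocyte samples.

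The split of the calls depended on scaling and on single libraries. With library totals alone, which moved the median log2 fold change of all tested transcripts from 0.03 to 0.15, 1506 transcripts were higher in neuron and 2130 higher in astrocyte samples, so that 41.4% of the calls were higher in neuron samples against 24.8% with TMM factors. Without neuron 1 or without neuron 2, where the lone neuron library was assumed to vary as the astrocyte pair did, there were 8959 and 6369 calls, of which 46.8% and 45.8% were higher in neuron samples. Without astrocyte 1 or astrocyte 2, where the spread came from the neuron pair alone, there were 1734 and 1523 calls, of which 11.1% and 10.9% were higher in neuron samples.

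**Figure D2:**
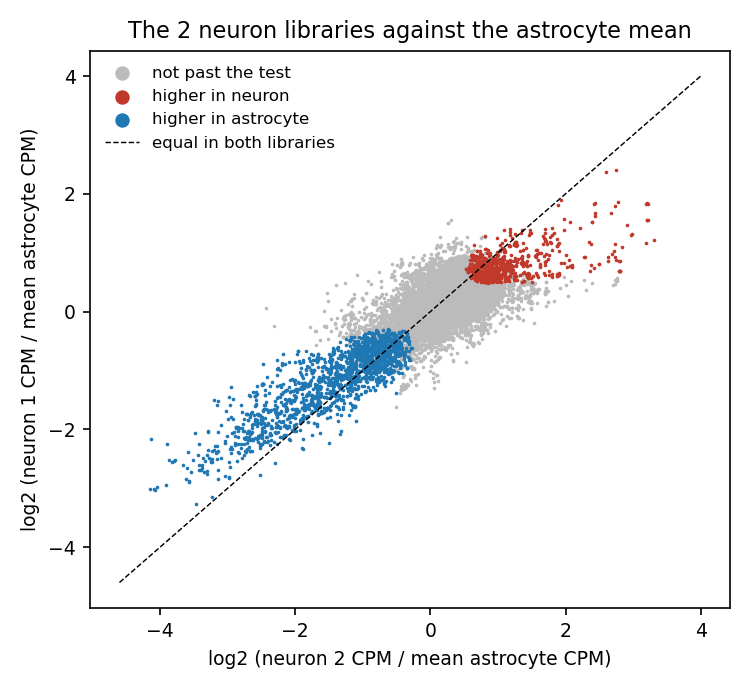
Each point is a transcript with a mean of at least 10 CPM, placed by the log2 ratio of neuron 2 (horizontal) and neuron 1 (vertical) to the mean of the astrocyte libraries. Red and blue points are calls higher in neuron and in astrocyte samples, and the dashed line marks equal ratios in both neuron libraries. Among all transcripts called higher in neuron samples, including those under 10 CPM that are not drawn, the median ratio to the astrocyte mean was 1.69 in neuron 1 and 2.00 in neuron 2.

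The second comparison asked how footprints were distributed over the 4 regions of a transcript, a question the study's title raises by naming alternative translation. Region b held 91.32% ± 0.322 of the counts in astrocyte and 92.44% ± 0.201 in neuron samples (SD, n = 2 each). Region a held 7.99% ± 0.309 in astrocyte and 6.87% ± 0.17 in neuron samples (SD, n = 2 each), and every astrocyte library lay above every neuron library. The shares of region a were 7.769% and 8.206% in astrocyte 1 and 2 and 6.987% and 6.746% in neuron 1 and 2, with 95% Wilson intervals of at most 0.0194 percentage points to either side. Regions c and d were small. Region c held 0.244% ± 0.0113 in astrocyte and 0.228% ± 0.0132 in neuron samples (SD, n = 2 each), and the groups overlapped. Region d held 0.444% ± 0.00113 in astrocyte and 0.470% ± 0.0169 in neuron samples (SD, n = 2 each) without overlap. The exact permutation p was 0.333 for regions a, b and d, the smallest that 2 against 2 libraries can give, and 0.667 for region c. The small differences of regions c and d moved with single libraries. The astrocyte minus neuron difference of region c, 0.0162 percentage points, was 0.0256 without neuron 1, 0.0069 without neuron 2 and 0.00827 without astrocyte 2, and that of region d, -0.0262 percentage points, was -0.0143 without neuron 1.

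With equal transcript weights in every library, region a held 7.24% ± 0.24 in astrocyte and 6.50% ± 0.156 in neuron samples (SD, n = 2 each), still without overlap. The difference of 0.745 percentage points compares with 1.04 over the same 13108 transcripts without equal weights. Over these transcripts without equal weights, region c held 0.241% and 0.220% in astrocyte and neuron samples without overlap. Region d held 0.398% and 0.414%, and its groups already overlapped. Regions c and d both overlapped between the groups at equal weights. Region c then held 0.232% and 0.2275% in astrocyte and neuron samples and region d 0.414% and 0.405%, and the direction of region d turned.

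**Figure D3:**
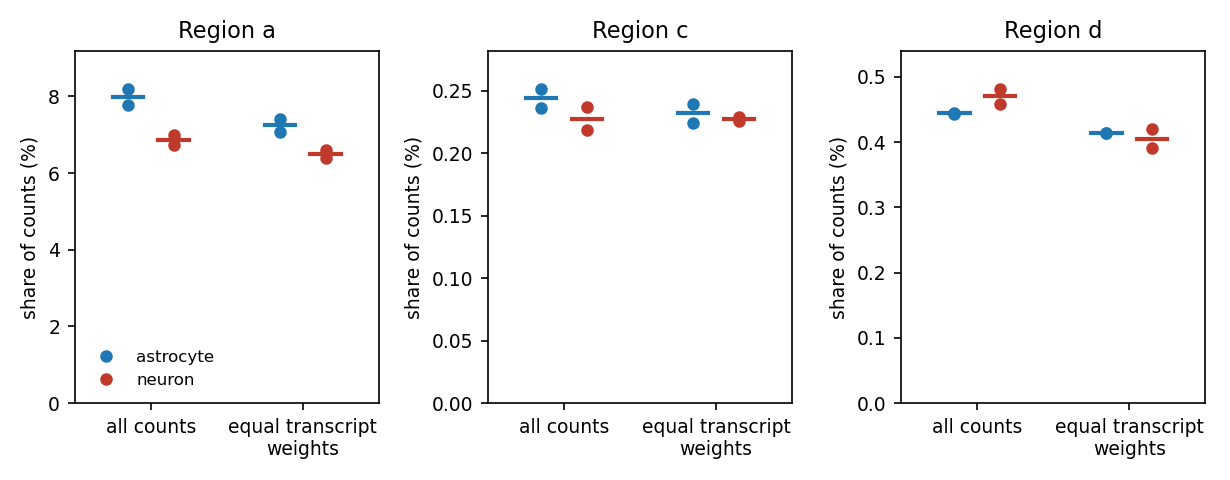
Points are libraries and bars are group means of the share of counts, in percent, that lay in regions a, c and d, over all counts and at equal transcript weights over 13108 transcripts. Only region a kept the astrocyte libraries above the neuron libraries in both.

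Per transcript, the ratio of region a to region b could be tested in 8778 transcripts. It changed in 95 transcripts, of which 89 had a higher ratio in astrocyte and 6 a higher ratio in neuron samples (edgeR quasi-likelihood test). These held 87 distinct profiles of region b counts, which may overstate the separate changes. ENSMUST00000004316, ENSMUST00000105465, ENSMUST00000177779 and ENSMUST00000179238, for example, each had 460 region a counts and a log2 change of -1.07, yet count as separate profiles. Over all 8778 transcripts the median log2 change was -0.215 and 70.6% lay below 0, that is lower in neuron samples. The changes that passed the test ranged in size from 0.73 to 3.52 on the log2 scale. The total count of the transcript also changed in 37 of the 95. The strongest, ENSMUST00000182764, chosen after its values were seen, had region a counts of 0.534% ± 0.375 of region b in neuron and 5.1% ± 0.457 in astrocyte samples (SD, n = 2 each), with an edgeR adjusted p = 2.48e-10. At an unadjusted p under 0.05 there were 947 transcripts with a higher ratio in astrocyte and 133 with a higher ratio in neuron samples, where 438.9 in all would be due to chance.

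The number of region a calls depended on the setting. DESeq2 called 10, and 12 were called when each region was scaled to its own total, a centring that takes out the shift shared by all transcripts and left a median of 0.025. Without astrocyte 1, astrocyte 2, neuron 1 or neuron 2 there were 1, 2, 207 and 48 calls. In these fits the lone library was assumed to vary as the complete pair did, and the cause of the differing numbers was not tested. Over the same fits the median log2 change stayed between -0.261 and -0.173.

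The ratio of region c to region b was testable in 290 transcripts, and edgeR and DESeq2 both called 0. At an unadjusted p under 0.05 edgeR gave 40, where 14.5 would be due to chance, and the median log2 change was -0.014. This median had no stable sign. It was -0.15 without astrocyte 1, 0.089 without astrocyte 2, -0.143 without neuron 1, 0.091 with each region's own total and 0.107 with no filter. With a mean count of at least 20 in both regions in place of the filter, edgeR called 5. The ratio of region d to region b changed in 1 of 544 transcripts, ENSMUST00000068791, named after its values were seen. It had 30 and 36 region d counts in neuron 1 and neuron 2 and 0 in the astrocyte libraries, with 255 region b counts in neuron and 231 in astrocyte samples. Against the 3 counts that a count of 0 allows over the group, its ratio was at least 19.9-fold higher in neuron samples (edgeR adjusted p = 0.0144). DESeq2 called 2 region d ratios, leaving out astrocyte 1, astrocyte 2 or neuron 1 gave 7, 5 and 0 calls under the same assumption on the lone library, and the median log2 change of -0.064 turned to 0.022 without neuron 2. Adjusted over all 3 regions together, 93, 0 and 5 ratios of regions a, c and d passed.

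**Figure D4:**
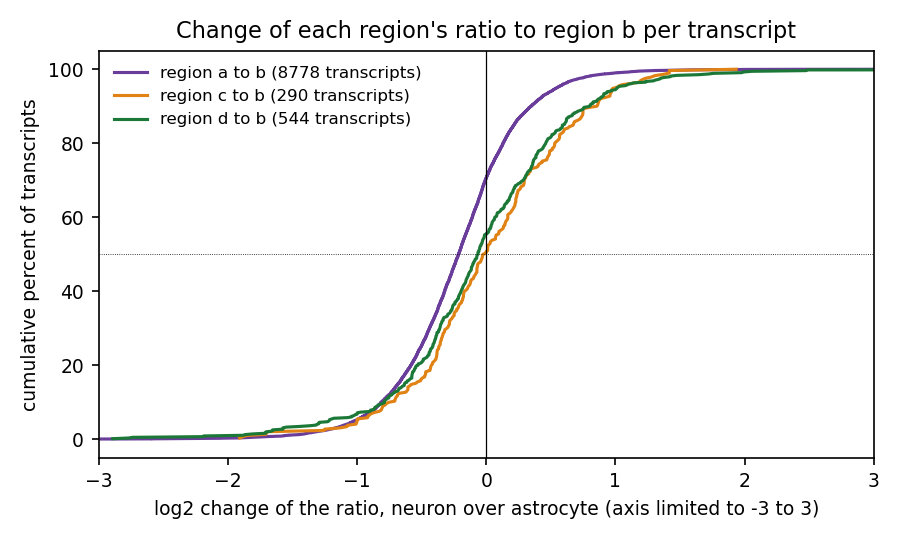
Lines give the cumulative percentage of transcripts (vertical axis) up to each log2 change of the ratio of region a, c or d to region b, neuron over astrocyte (horizontal axis). The dotted line marks the median, which lies at -0.215 for region a, -0.014 for region c and -0.064 for region d.

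The levels of the regions varied widely between transcripts. Among 7382 transcripts with at least 1000 region b counts, the median count of region a was 4.24% of that of region b, that of region c 0.0386% and that of region d 0.0944%. No count at all was found for region a in 382 of these, for region c in 3122 and for region d in 2012. Region a exceeded 10% of region b in every library in 1250 transcripts, region c in 10 and region d in 33. It exceeded region b itself in every library in 9 transcripts for region a and in 1 each for regions c and d. These last were ENSMUST00000173041, with region c at 129.5% to 194.4% of region b, and ENSMUST00000068792, with region d at 138.5% to 252.9%, both chosen after their values were seen. Where both cell types had at least 20 counts in the region, its level relative to region b ranked transcripts alike in both. Spearman rho across transcripts, which are not independent replicates, was 0.939 for region a (4919 transcripts), 0.949 for region c (143) and 0.969 for region d (228). This rule leaves out transcripts with few region counts in either cell type. The ranking therefore says nothing of regions counted in 1 cell type only, and for regions c and d it covers few of the 7382 transcripts.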

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

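Region b counts alone, 1 transcript per set, the crossed pairing and the alternatives of the region a, c and d ratios and shares, except that of at least 100 region b counts, were chosen after seeing the data. No transcript called in the main comparison changed direction in any of the 18 alternatives that tested it. As the calls were made in these same libraries, that outcome was largely fixed in advance. The 4 named transcripts of that comparison passed the test in every alternative that tested them with all 4 libraries. As they were picked from these same libraries for large fold changes without overlap, this was largely set by the choice. The number of changed transcripts, 3219, stayed within 1.5 times in 13 of 18 alternatives, those higher in neuron in 9 and those higher in astrocyte samples in 14. A minimum fold of 1.5 left 1385 calls, 107 higher in neuron and 1278 higher in astrocyte samples. Those higher in neuron samples numbered 1506 with library totals alone, 458 among transcripts with a mean of at least 10 CPM and 530 with 1 transcript per set. The last 2 settings tested fewer transcripts than the main comparison, 13354 and 15510. The setting with 1 transcript per set also used region b counts only, which without removal of repeats gave 633. With 1 library left out, calls ranged from 1523 to 8959, those higher in neuron from 166 to 4193 and those higher in astrocyte samples from 1357 to 4766. The cause was not tested beyond the tests of scaling and spread given under the other observations.

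Replicate numbers 1 and 2 occur in both groups, but no label says that they pair samples, and deviations of same-numbered libraries correlated at r = -0.081 (Spearman rho = -0.119) across 18819 transcripts. The replicate block gave 3417 calls. The crossed pairing gave 4351, of which 1355 were higher in neuron samples.

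For the region a ratio, each region's own total left 12 calls and reversed the median to 0.025, by its construction, and DESeq2 left 10. With 1 library left out, calls ranged from 1 to 207. The median kept its sign in the other 10 of 11 alternatives. Region c gave 5 calls with a mean count of at least 20. Region d gave 5 calls with each region's own total, 2 with DESeq2, 6 with the replicate block and 5 with 1 transcript per set. It gave 0 with no filter, and 0 with a mean count of at least 20 or at least 100 region b counts, 2 settings that leave out the called transcript. With 1 library left out it gave 0 to 7. The median was -0.125 with each region's own total, -0.043 with a mean count of at least 20 and -0.096 with at least 100 region b counts, and turned to 0.075 with no filter. With 1 library left out that median lay between -0.122 and 0.022. The region a share stayed 0.903 to 1.34 percentage points higher in astrocyte samples. The region d share differed by -0.0262 percentage points, astrocyte minus neuron, and by -0.00581 without the 500 most abundant transcripts. For these the cause was not tested. Depth limits regions c and d, which hold under 0.5% of the counts each, so that 290 and 544 transcripts could be tested.

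Not run, for lack of gene names, were all alternatives of the gene list tests and marker shares and the removal of mitochondrially encoded genes. The 2 transcripts of the 4 named that share counts with others were not tested in the setting that keeps 1 per set.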

Other observations

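The share of astrocyte-type RNA, the region a shares at equal weights, the background comparison and its bound, the ratio in classes called on region b counts, the fold ceiling and the meaning of region b were tested only after the result was seen. Leaving out each library was planned, and its use as a test of the imbalance of calls was chosen after the result was seen.

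Region c and region d counts were concentrated in few transcripts. The 10 transcripts with most counts held 17.4% of region c and 13.1% of region d counts, against 4.0% of region a and 3.33% of region b counts. Only 1281 of the 7888 transcripts with a region c count had one in every library, and 2396 of the 10981 with a region d count. Some transcripts had footprints in other regions and none in region b: 957 transcripts had no region b count in any library, and these held 0.271% of all counts. Members of a set with identical region b counts often differed elsewhere, in region a in 1664 of 1983 sets, in region d in 430 and in region c in 72.

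The neuron libraries differed more from each other than the astrocyte libraries did: among 13354 transcripts with a mean of at least 10 CPM, 13 were over 4-fold higher in neuron 2 than in neuron 1, 2 were over 4-fold higher in neuron 1, and 0 differed this much between the astrocyte libraries. Depth is argued against, since thinning every library to the smallest total left the SD of log2 differences 1.63 times as large in the neuron pair. Neuron 1 lay between the astrocyte mean and neuron 2 in 83.6% of the transcripts called higher in neuron and 70.7% of those called higher in astrocyte samples, as mixing would give. A single share of astrocyte-type RNA in neuron 1 would have to be equal for all transcripts. The transcripts higher in neuron needed a median of 33.5% (bootstrap 95% interval 31.1% to 36.5%) and those higher in astrocyte samples 8.19% (7.64% to 9.37%). The intervals come from resampling transcripts, which are not independent, and do not cover the spread between pools. The ratio of the 2 estimates, 4.09, stayed at 2.77 or more over 4 scalings. Both sets were called in these same libraries, by a test that passes transcripts more readily where the neuron libraries agree. As this selection may lower the 2 estimates unequally, their difference cannot decide on mixing, which stays open. Different shares of neuron types in the pools and a difference between the experiments also stay open and were not tested, as neither marker genes nor a batch label could be used.

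More transcripts were called higher in astrocyte than in neuron samples, and this imbalance may have a technical part among small changes. With library totals alone 41.4% of calls were higher in neuron samples, and with either neuron library left out at least 45.8% were, so scaling and the spread between the neuron libraries both stay open as explanations of the counts of calls. For transcripts at least 2-fold apart, an aspect separated after these values were seen, both are argued against: 15.0% of 2485 such transcripts, called or not, were higher in neuron samples, and at most 23.3% were under any of the 3 other scalings. With no filter on counts the share higher in neuron samples was larger, 31% of 4936 such transcripts, and still the minority. A hypothesis that stays open is neuron-type RNA in the astrocyte libraries, which would put a ceiling on folds toward neurons: among 9848 transcripts with a mean neuron level of at least 20 CPM the highest ratio of mean CPM, taken without TMM factors and so not on the scale of the fitted folds, was 6.43 for neuron over astrocyte, which allows a share of up to 15.5%. The highest such ratio of astrocyte over neuron, at a mean astrocyte level of at least 20 CPM, was 11, and a biological difference, with more transcripts of high specificity in astrocytes, would look alike and was not tested.

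Region a took a larger share of counts in the astrocyte libraries, and the abundance of transcripts rich in region a accounts for part of this at most, since 0.745 percentage points were left at equal weights. Fragments counted at several transcripts with identical counts are argued against: repeats held 10.0% to 10.5% of the region a counts of a library, and with repeats taken out of each region the difference was 1.20 percentage points (larger SD 0.314). Background fragments that raise every region outside b cannot be told apart from a change of region a alone, since the highest astrocyte to neuron ratio of regions c and d over pairs of libraries, 1.062, lay below the lowest of region a, 1.07, by less than the spread of these ratios (SD 0.0424). The measured shift of the ratio of region a to region b was not uniform. Among transcripts called on region b counts alone, the median log2 change was -0.310 in those higher in astrocyte and -0.087 in those higher in neuron samples. The difference was 0.223 (0.177 to 0.206 in the 4 pairs of an astrocyte and a neuron library, from unmodelled ratios). Neuron-type RNA in the astrocyte libraries, left open above, would shrink a uniform shift most in transcripts higher in neuron samples. The class difference therefore cannot decide whether the shift between the cell types themselves is uniform. A difference between cell types in ribosome occupancy of region a, fragments shared with transcripts whose counts are not identical, and a difference in digestion between the lines' experiments remain open, and were not tested.

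A further hypothesis is that region b is the coding sequence, where footprints are known to concentrate. The lowest share of region b in any library was 91.1%, but as the lengths of the regions are not given in the sources used here, a long region of another kind would give the same value.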
